A study of Rattus norvegicus with 4 samples.

How the data were processed

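RNA from 4 libraries of the rat line NRK-52E was sequenced, 2 titled lv_nc and 2 titled lv_Mettl3. Per the labels' protocols, murine Mettl3 cDNA was delivered by lentivirus collected 48 h after transfection of the packaging cells, with selection at 0.5 mg/ml and maintenance at 0.25 mg/ml puromycin in medium with 10% serum. The labels name the molecule as polyA RNA, while the series text describes mRNA purified after removal of ribosomal RNA, and the library kit and strand setting are not given in the sources used here. All 4 samples carry the treatment label untreated. Groups and replicate numbers were taken from the titles.

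Per the submitters' processing notes, reads were processed with CASAVA 1.4 and HISAT2. The counter, genome build and annotation release are not given in the sources used here. The deposited table lists 17768 genes, 945 of them unnamed transcripts. Its library columns hold a signal that the authors made by dividing gene read counts by 1 size factor per library: within a tolerance of 0.001 reads, 100% of the values of each library were whole multiples of that library's smallest positive value. Whole reads were recovered with these steps, and size factors were 1.02, 1.08, 0.943 and 0.968 in lv_nc replicates 1 and 2 and lv_Mettl3 replicates 1 and 2. The deposited log2 fold changes and p-values are the authors' own, per the file headers; the tool is not named. The 5167 genes given an adjusted p of 1 by the authors were those for which DESeq2 on the recovered reads gave NA. Gene lengths, in bases, are as deposited by the authors. No coordinates were converted.

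The test planned for raw counts before the data were examined was the edgeR quasi-likelihood test, with limma planned for normalized values. Because the file holds normalized values, and so differs from the counts the design assumed, the test used was limma 3.58.1 (trend) on log2(value + 1), over genes with a value of at least 1 in at least 2 libraries, with Benjamini-Hochberg adjustment at 0.05. Fold changes from limma are on that log2 scale, which understates the change of low genes. Count tests on the recovered reads were run as alternatives: DESeq2 1.42.0 called 318 genes and edgeR 4.0.16 called 5. The DESeq2 calls are described beside those of limma because limma called 3; that decision was made after the results were seen. Rose and fell are used of genes called by the test named with them. R was 4.3.3, Python 3.11.15 and matplotlib 3.10.9.

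A total of 28 gene lists were fixed before the data were examined, and 923 of 1088 symbols were found in the table by exact symbol, and a lookup of the rest through Ensembl identifiers of current or older names found 0 more. Camera had been planned on counts, and was run on the limma values at a preset correlation of 0.01, adjusted over the lists, with camera on edgeR counts as an alternative. With an estimated correlation 0 of the 6 called lists was called, and 0 with fry, which tests whether a list's genes move one way on balance. With an estimated correlation camera has only the residual degrees of freedom of 4 libraries, and its smallest adjusted p was 0.446. The unfolded protein list had that value at an estimated correlation of -0.0189, below the preset 0.01. A call lost in that setting therefore does not show that correlation between genes made the shift, nor does it back the preset. Named genes were, by a rule fixed before the data were examined, Mettl3 and called writer partners, the 10 largest changes in each direction among called genes with separated groups and a mean of at least 5 CPM in the higher group, the 6 next smallest adjusted p-values, and up to 4 called members of each list, or up to 2 abundant members where none was called. A withheld gene that this rule picked is not reported here. Locus-type names, pseudogenes and mitochondrial or ribosomal RNA genes were left out of the ranked part. Applying the rule to the DESeq2 calls was decided after the results were seen.

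Scripts were tested on simulated counts for lv_Mettl3 against lv_nc, with 13113 genes drawn from the real means and dispersions and 200 changed among those with a mean of at least 50. Limma recovered 64 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 7.51% false calls. DESeq2 recovered 71 and 98 with 12.4% false calls. Both shares were above the nominal 5% in this single simulated set, that of DESeq2 by more. A single set does not give the false call rate of either test, nor rank them. The simulation uses dispersions shrunk across genes, so real genes can vary more. In the simulated lists a shift of 1.5-fold in 40 genes gave a camera p of 4.73e-25, and 3 of 100 unshifted lists had a p under 0.05. Each simulated gene was drawn independently, whereas estimated correlations in the real lists reached 0.375 for autophagy and 0.648 for interferon genes. The simulation therefore cannot show the false positive rate of camera for lists whose genes vary together.

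Alternatives changed the scaling, filters, pseudocount, gene set, test, threshold, replicate block and the libraries used. DESeq2's own size factors are the deposited scale and so were not a separate setting. Replicates differed by more than counting error in both groups, with a chi-square per degree of freedom of 28.6 in lv_nc and 7.54 in lv_Mettl3. That covers counting error only, which separate libraries are expected to exceed, and was used only to see whether 2 columns could hold the same library. Where the genes of a pair are near-identical or overlap, the deposited counts cannot separate them.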

Results

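RNA sequencing was carried out on 4 libraries of NRK-52E, an established epithelial line from normal rat kidney that keeps features of the proximal tubule. The libraries fall into 2 groups of 2 by their titles, lv_nc and lv_Mettl3. Per the labels, a lentivirus carrying a murine Mettl3 cDNA was used to make a stable line under puromycin. Mettl3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on RNA. The labels do not say what nc stands for, nor whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The recovered gene reads per library were 16133328 and 16622255 in lv_nc replicates 1 and 2, and 15068898 and 15483756 in lv_Mettl3 replicates 1 and 2. Values below are normalized read counts, with means ± SD (n = 2 libraries per group).

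The lv_nc libraries differed from each other more than the lv_Mettl3 libraries did. Over 10050 genes with a mean of at least 100, the SD of the log2 difference between replicates was 0.41 in lv_nc and 0.29 in lv_Mettl3. Across these genes, which are not independent replicates, Pearson's r was 0.967 between the lv_nc libraries and 0.984 between the lv_Mettl3 libraries. It was 0.981 between lv_nc replicate 1 and lv_Mettl3 replicate 1, and 0.947 between lv_nc replicate 2 and lv_Mettl3 replicate 1, so lv_nc replicate 1 was closer to that library than to its own replicate. Mitochondrially encoded genes took 2.20% and 2.03% of the reads in lv_nc and 2.33% and 2.07% in lv_Mettl3.

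Mettl3 mRNA was not higher in the libraries labelled lv_Mettl3. The gene (ENSRNOG00000013111, chromosome 15, 28710300 to 28721127 as the authors' file gives it, build not given in the sources used here) had normalized counts of 719 and 767 in the lv_nc libraries and 757 and 700 in the lv_Mettl3 libraries. The means were 743 ± 34.0 and 728 ± 40.6, a log2 fold change of -0.03 (SE 0.11, limma adjusted p = 0.931), smaller than the spread between replicates. The highest library was 1.10 times the lowest. Because the titled gene does not separate the groups, the groups are called by their labels throughout, and each direction below is that of the libraries labelled lv_Mettl3 relative to those labelled lv_nc. Whether reads from the murine cDNA were assigned to the rat gene was not analysed here.

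Among the other components of the m6A machinery 1 gene was called with adjustment over all genes. The writer list holds partners of the Mettl3 complex. It also holds genes of other RNA methyltransferases that act outside that complex (Mettl16, Mettl5 with Trmt112, Zcchc4 and Pcif1). Of its 12 genes, limma called 0, and 0 adjusted over the list alone. DESeq2 called 1, Rbm15b, an adaptor that directs the complex to RNA, which rose from 952 ± 123 to 1448 ± 164 (DESeq2 log2 fold change 0.61, SE 0.18, adjusted p = 0.0417; limma adjusted p = 0.399). Of 17 erasers and readers, limma and DESeq2 each called 0. Adjusted over the list alone, limma called 0 and DESeq2 called 1, which was lower. The reader Hnrnpa2b1 had 9949 ± 450 in lv_nc and 9747 ± 3.95 in lv_Mettl3. The camera adjusted p was 0.364 for the writer list and 0.588 for the erasers and readers, and 0.93 for both with an estimated correlation.

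**Figure D1:**
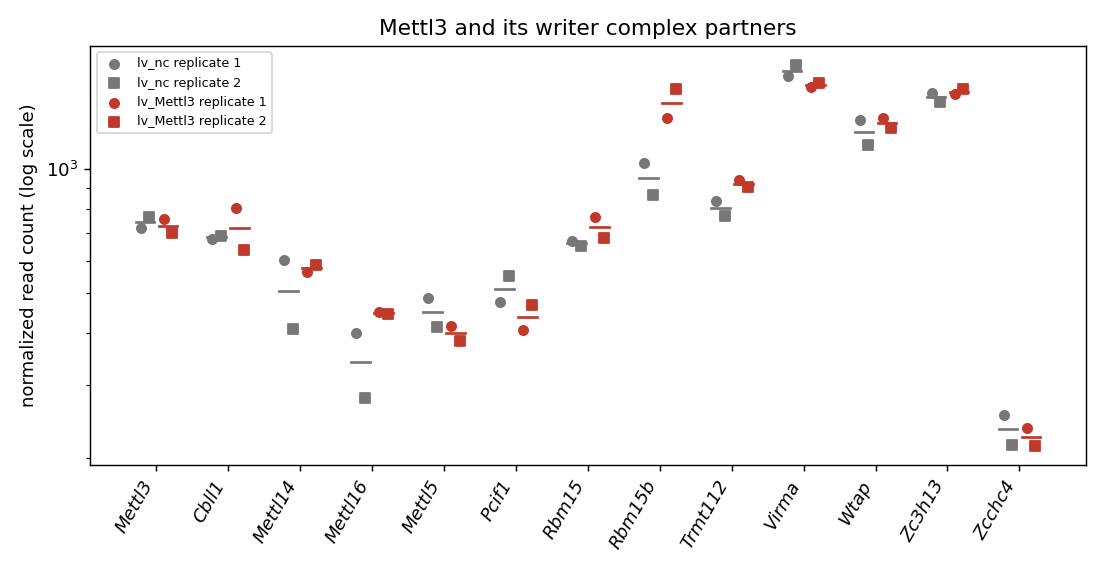
Normalized read count (log axis) of Mettl3 and the 12 genes of the writer list in each library, with lv_nc in grey and lv_Mettl3 in red, circles for replicate 1, squares for replicate 2 and bars for group means. Mettl3 lay between 700 and 767 in the 4 libraries.

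Which genes differed between the groups was asked across the whole table. The genes that passed limma's test were Cck, Cxcl10 and LOC103694902. Cck, which encodes the peptide hormone cholecystokinin (ENSRNOG00000019321, chromosome 8, 130120523 to 130127392), rose from 1277 ± 143 to 7003 ± 259, a log2 fold change of 2.46 (SE 0.11, limma adjusted p = 0.0257). Cxcl10, an interferon-induced chemokine (ENSRNOG00000022256, chromosome 14, 17210733 to 17212930), rose from 7511 ± 540 to 34817 ± 3282, a log2 fold change of 2.21 (SE 0.11, limma adjusted p = 0.0342). The limma adjusted p of Cxcl10 was 0.0502 with library size scaling and 0.0506 with a replicate block, at log2 fold changes of 2.17 and 2.21, so its call ended in both, while Cck and LOC103694902 kept theirs. LOC103694902, described in the file as ubiquitin-conjugating enzyme E2 B, rose from 33.6 ± 3.35 to 818 ± 127 (limma log2 fold change 4.56, SE 0.21, adjusted p = 0.0257). LOC103694902 lies outside the assembled chromosomes, on AABR07024291.1, falls outside the naming rule and was named after its values were seen. A search of the table found no gene of the same name or description, but copies described in other words would be missed by it, so its value stays uncertain.

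These 3 genes were all that limma called among 16391 tested, all higher and all by at least 2-fold. At an unadjusted p under 0.05, 908 genes were higher and 808 lower. The quasi-likelihood test of edgeR on the recovered reads called 5 genes, all higher (these 3, Rtp3 and Ccl2), and 1530 at an unadjusted p under 0.05. The limma count fell to 0 with a pseudocount of 0.1, and was 24 with robust empirical Bayes. Without 1 library, which leaves 1 in a group, limma log2 fold changes were 2.344 to 2.572 for Cck and 2.115 to 2.308 for Cxcl10. For LOC103694902 they were 4.4 to 4.717. DESeq2 on the same reads called 318 genes, 183 higher and 135 lower (57.5% higher), including 167 at 2-fold or more, of which 90 were higher and 77 lower. The DESeq2 count was 1547 without lv_nc replicate 1 (865 higher, 682 lower), 217 without lv_nc replicate 2 (164 higher, 53 lower), 56 without lv_Mettl3 replicate 1 (39 higher, 17 lower) and 61 without lv_Mettl3 replicate 2 (39 higher, 22 lower). Of the 318, 316 had both libraries of a group above both of the other. Selection on the same values largely brings this about, so it lends the calls no separate weight. Among all genes tested by limma that share was 45%, where chance gives 33.3% if the libraries are exchangeable.

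Among the genes that rose in DESeq2 were Tnip3, an inhibitor of NF-kB signalling (79.1 ± 40.1 to 663 ± 42.0, DESeq2 adjusted p = 5.22e-20), Nts, which encodes neurotensin (33.8 ± 6.05 to 196 ± 0.144, adjusted p = 2.43e-08), and Rtp3 (231 ± 25.6 to 1069 ± 11.2, adjusted p = 1.39e-24). The chemokine gene Ccl4 rose from 10.2 ± 10.5 to 79.9 ± 14.1. Also among the 10 largest increases that met the naming rule, which left out some larger ones, were Slc25a22 (10.4 ± 0.925 to 94.7 ± 63.4), Epb41l1 (16.7 ± 5.37 to 96.8 ± 60.4), Fgd1 (20.3 ± 19.6 to 103 ± 72.1) and Miip (10.1 ± 6.45 to 164 ± 73.3). These sizes are uncertain. Without 1 library the limma log2 fold change lay between 2.112 and 4.413 for Ccl4, 2.16 and 3.62 for Slc25a22, and 1.67 and 3.02 for Epb41l1. It lay between 1.36 and 3.60 for Fgd1, and 3.325 and 4.584 for Miip. Hprt1, a purine salvage enzyme, and Senp5, a SUMO protease, were 36.7-fold and 28.8-fold higher, from counts of 4.32 ± 2.19 and 2.85 ± 0.114. Hprt1 ranged widely between the lv_Mettl3 libraries (271 and 45.5). Senp5 is uncertain, since LOC103689978, also on chromosome 11, is described as sentrin-specific protease 5. Both have a deposited length of 2253 bases, and reads could be split between them. LOC103689978 had 2.93 and 0.923 in the lv_nc libraries and 10.6 and 87.8 in the lv_Mettl3 libraries, so both genes were higher in lv_Mettl3. A split between them would change the size of each rather than the shared direction. Reads from other copies stay possible.

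Among the genes that fell in DESeq2 were Duox2, an NADPH oxidase (218 ± 136 to 26.04 ± 14.3, DESeq2 adjusted p = 8.87e-07), Myo7a, an unconventional myosin (237 ± 78.4 to 27.8 ± 2.72, adjusted p = 4.57e-11), Dhrs3, a retinal reductase (193 ± 151 to 29.2 ± 11.3, adjusted p = 0.000143), and Ssc5d (129 ± 88.8 to 22.1 ± 7.80) and Brms1 (109 ± 27.9 to 20.9 ± 5.54). Without 1 library limma log2 fold changes were -3.655 to -2.296 for Duox2, -3.365 to -1.578 for Dhrs3 and -3.108 to -1.591 for Ssc5d. The sizes of these falls are uncertain. Gstm3, Tbcb and Pdcd5 fell from 353 ± 271, 140 ± 36.0 and 468 ± 237 to 4.72 ± 0.826, 3.13 ± 1.42 and 66.7 ± 22.7. Their limma log2 fold changes without 1 library were -6.584 to -4.834, -5.471 to -4.753 and -3.274 to -2.195. Gstm3 and Pdcd5 each have a same-described copy in the table and are also uncertain for that reason. No such copy was found for Tbcb, nor for Hprt1 above, but copies described in other words would be missed. Tbcb and Hprt1 are therefore uncertain as well. No gene of this paragraph or the one before it was called in the main limma fit. Rtp3 was called by edgeR (adjusted p = 0.0133), by limma-voom (0.0198) and by limma with TMM scaling (0.0432), at least 1 CPM in all 4 libraries (0.0156), protein-coding genes only (0.0407) and robust empirical Bayes (0.00951), and Tnip3, Nts, Senp5, Myo7a, Tbcb and Gstm3 by limma with robust empirical Bayes, each at an adjusted p between 0.0416 and 0.0479.

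NF-kB inflammatory genes were higher as a group. Of 43 tested, DESeq2 called 12, all higher, limma called 1 (Cxcl10), and limma adjusted over the list alone called 13, all higher. Besides Cxcl10, the monocyte chemokine gene Ccl2 rose from 413 ± 57.3 to 1741 ± 103, the neutrophil chemokine gene Cxcl1 from 415 ± 83.7 to 1178 ± 30.2 and the macrophage growth factor gene Csf1 from 856 ± 96.7 to 2092 ± 1.64 (DESeq2 adjusted p = 8.39e-26, 1.17e-10 and 1.81e-11; limma adjusted p = 0.0673, 0.165 and 0.162). The median log2 fold change was 0.49 (camera adjusted p = 3.51e-10; adjusted p = 0.446 with an estimated correlation).

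Interferon response genes were called in both directions by DESeq2. Of 52 tested, DESeq2 called 11 higher and 3 lower, limma called 0 with either sign, and limma adjusted over the list alone called 10 higher and 2 lower, and DESeq2 adjusted that way 11 higher and 5 lower. Herc6 rose from 297 ± 71.4 to 1109 ± 78.6, Ifit3 from 103 ± 3.91 to 426 ± 75.8, Oasl from 1388 ± 375 to 3583 ± 200 and Isg15 from 1889 ± 404 to 4212 ± 144, with DESeq2 adjusted p between 5.24e-15 and 2.43e-08. Isg15 encodes a ubiquitin-like modifier, Herc6 a ligase of the same system, and Ifit3 and Oasl belong to antiviral gene families. The 3 lower genes were Ly6e, Bst2 and Lgals3bp, with DESeq2 log2 fold changes of -1.09, -0.71 and -0.62. The camera adjusted p was 0.0796 (adjusted p = 0.93 with an estimated correlation). It was 2.25e-08, upward, without lv_nc replicate 2, 0.515, downward, without lv_nc replicate 1, and 0.000774 with camera on edgeR counts.

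The immediate early list holds Fos and Egr1 and also genes of kinase feedback and later response, such as Spry2, Dusp6, Etv4 and Etv5. Its genes were higher as a group, with 28 of 38 above 0 in log2 fold change. Of these 38, DESeq2 called 9, all higher, limma 0, and limma adjusted over the list alone 12, all higher. DESeq2 adjusted over the list alone called 13 higher and 1, Fos, lower. The ETS factor genes Etv5 and Etv4 rose from 292 ± 89.6 to 968 ± 41.7 and from 580 ± 239 to 1516 ± 19.2, the AP-1 gene Fosl1 from 291 ± 49.9 to 760 ± 148, and Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, from 313 ± 56.8 to 651 ± 19.2 (DESeq2 adjusted p = 1.69e-10, 4.46e-06, 1.29e-06 and 0.000348). Fos and Egr1, named after their values were seen, had limma log2 fold changes of -0.89 and -0.57 and were called by neither limma nor DESeq2 with adjustment over all genes. The list median was 0.35 (camera adjusted p = 3.6e-06; adjusted p = 0.446 with an estimated correlation).

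Genes of the unfolded protein and integrated stress response were higher as a group by smaller amounts. Of 44 tested, DESeq2 called 6, all higher, limma 0, and limma adjusted over the list alone 12, all higher. The endoplasmic reticulum chaperone genes Hspa5 and Hyou1 rose from 36703 ± 1215 to 52444 ± 1400 and from 8184 ± 315 to 12708 ± 85.2, Creld2 from 2875 ± 47.4 to 5526 ± 64.6 and Dnajb9 from 363 ± 33.8 to 613 ± 17.0 (DESeq2 adjusted p = 0.00712, 0.000336, 8.25e-09 and 0.0205). The list median was 0.28 (camera adjusted p = 2.75e-09; adjusted p = 0.446 with an estimated correlation).

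Extracellular matrix genes were lower as a group. Of 45 tested, DESeq2 called 7, all lower, limma 0, and limma adjusted over the list alone 6, all lower. Col1a1 and Col3a1, which encode fibrillar collagen chains, fell from 6310 ± 3389 to 955 ± 111 and from 5215 ± 1556 to 1201 ± 261. Timp3, a metalloproteinase inhibitor, fell from 358 ± 113 to 125 ± 17.8, and Fbln5, an elastic fibre protein, from 3024 ± 400 to 1709 ± 112 (DESeq2 adjusted p = 0.000199, 2.37e-19, 0.00021 and 0.000107). Col1a1 was at 3914 and 8706 in the lv_nc libraries. DESeq2 adjusted over the list alone called 10 lower and 1 higher. The list median was -0.25 (camera adjusted p = 3.41e-05; adjusted p = 0.562 with an estimated correlation).

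Fibroblast and smooth muscle markers, some of which are also matrix genes, were lower by camera (adjusted p = 0.0251; adjusted p = 0.562 with an estimated correlation). Of 18 tested, DESeq2 called 4, all lower: Col1a1, Col3a1, Col1a2 (110 ± 34.5 to 22.6 ± 8.55) and Acta2, smooth muscle actin (1139 ± 554 to 515 ± 38.2). Limma called 0, and 5 adjusted over the list alone, all lower. The camera adjusted p was 0.0544 with a filter of at least 1 CPM in all 4 libraries, 0.0916 without lv_nc replicate 1, 0.0947 without lv_Mettl3 replicate 1 and 0.0576 without lv_Mettl3 replicate 2. Autophagy and lysosome genes were lower by camera (adjusted p = 0.0251; adjusted p = 0.93 with an estimated correlation), with a median of -0.11, and of 49 tested neither limma nor DESeq2 called any. Ctsb and Ctsl, lysosomal proteases, had 13822 ± 924 and 17176 ± 2131 in lv_nc and 13933 ± 792 and 18720 ± 1172 in lv_Mettl3. Adjusted over the list alone limma called 0. The camera adjusted p of that list was 0.915 without lv_nc replicate 2 and 0.357 without lv_Mettl3 replicate 1.

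**Figure D2:**
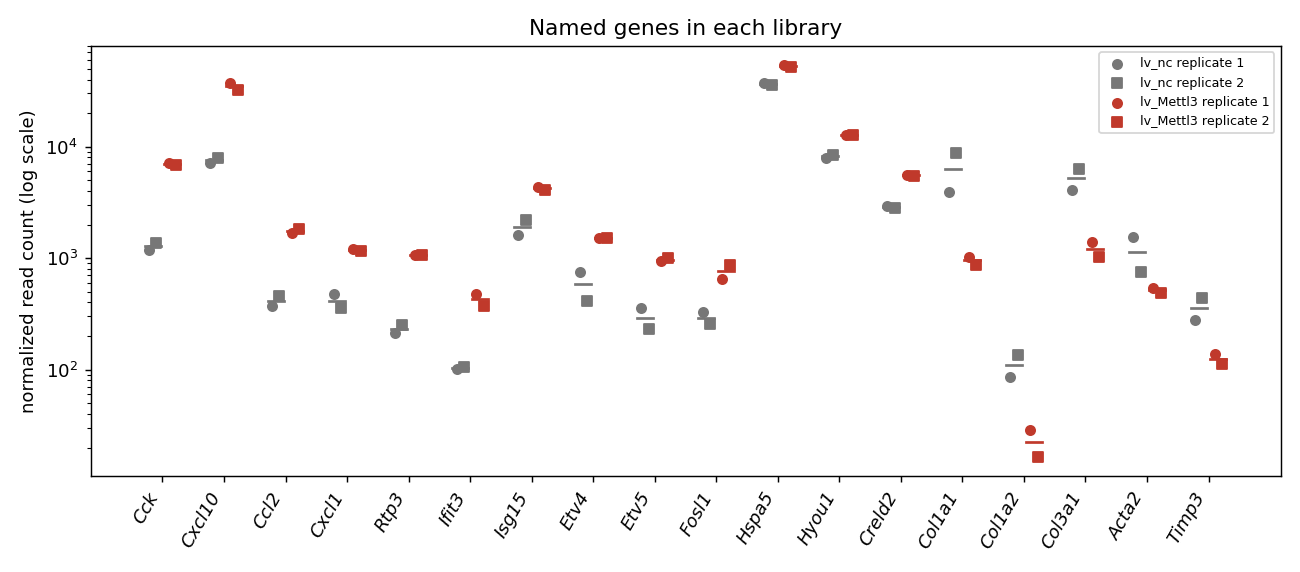
Normalized read count (log axis) of 18 named genes in each library, with lv_nc in grey and lv_Mettl3 in red, circles for replicate 1, squares for replicate 2 and bars for group means. Cxcl10 had means of 7511 and 34817, and Col1a1 of 6310 and 955.

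No kidney epithelial list passed camera's threshold, and limma called 0 genes of these lists. Of 28 proximal tubule genes tested, DESeq2 called 1, Ggt1, a brush border peptidase (2471 ± 83.6 to 3526 ± 328, DESeq2 adjusted p = 0.0345), and the camera adjusted p was 0.929, with a list median of -0.04 although the direction of the test was up. Of 12 loop, distal tubule and collecting duct markers DESeq2 called 0 (camera adjusted p = 0.649), with Wnk1 at 6832 ± 1101 and 8616 ± 664. Of 22 tubular injury genes DESeq2 called 2, both higher: Clu (14348 ± 967 to 21168 ± 451) and Plaur (1003 ± 34.1 to 1504 ± 174), with a camera adjusted p of 0.142 that was 0.0197 with camera on edgeR counts. Adjusted over the list alone, limma called 2 tubular injury genes, both higher, and 0 in the other lists of this paragraph, and DESeq2 called 5 tubular injury genes higher and 1 lower. Epithelial junction genes (27 tested, camera adjusted p = 0.289) had no call, with Tjp1 at 11335 ± 611 and 12287 ± 129. Endothelial, leukocyte and podocyte markers (15 tested, adjusted p = 0.142) also had none, and their adjusted p was 0.00765, upward, without lv_Mettl3 replicate 1. Cd14 was at 1952 ± 249 and 2033 ± 74.2.

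Of 26 mesenchymal transition genes DESeq2 called 2, Acta2 and Snai1, a repressor of epithelial genes (233 ± 77.2 to 91.6 ± 3.88, DESeq2 adjusted p = 0.00902), both lower (camera adjusted p = 0.929). Of 28 TGF-beta responsive genes it called Ltbp4 and Ltbp3, which bind latent TGF-beta, both lower (camera adjusted p = 0.815, downward, with a median of -0.01 and a mean of 0.05). Of 29 p53 and senescence genes it called Plk3, Plk2 and Pmaip1, all higher (camera adjusted p = 0.142, and 0.0294 without lv_nc replicate 2), and of 35 apoptosis genes Ripk3, a kinase of necroptosis, which was higher (camera adjusted p = 0.316). Of 30 NRF2 antioxidant genes it called Akr1b8 (2869 ± 554 to 7472 ± 359), Aldh3a1 (222 ± 37.8 to 609 ± 80.6) and Nqo1 (7921 ± 305 to 11287 ± 789), all higher, with a camera adjusted p of 0.0773 that was 0.00358 without lv_nc replicate 2 and 0.0087 with camera on edgeR counts. None of the genes in this paragraph was called by limma. Adjusted over the list alone it called 3 NRF2 genes, all higher, and 0 in the other lists of this paragraph, and DESeq2 called 4 NRF2 genes higher and 1 more apoptosis gene, which was lower.

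Metabolic and proliferation lists held few calls. Of 35 glycolysis and hypoxia genes DESeq2 called Car9, a carbonic anhydrase, which fell from 10720 ± 609 to 7840 ± 126, and of 36 cholesterol and fatty acid synthesis genes Scd2, a desaturase, which fell from 27384 ± 6685 to 17414 ± 764 (camera adjusted p = 0.351 and 0.527). It called 0 of 52 cell cycle genes (0.728), 0 of 43 oxidative phosphorylation genes (0.148), 0 of 36 fatty acid oxidation genes (0.0503) and 0 of 27 ferroptosis genes (0.142). Top2a had 14493 ± 4305 and 14796 ± 3306, Atp5f1b 16806 ± 244 and 16191 ± 365, and Tfrc 6204 ± 2120 and 8326 ± 821. The cell cycle adjusted p was 0.000566, and that of glycolysis and hypoxia 0.00404, without lv_nc replicate 2, and that of fatty acid oxidation 0.000187 without lv_nc replicate 1. The cell cycle list had a median of 0.02 with a downward test, and glycolysis and hypoxia a mean of -0.0037 with an upward test. Composition lists of 13 mitochondrially encoded, 75 ribosomal protein and 15 histone genes had no call (camera adjusted p = 0.148, 0.364 and 0.776). The ribosomal protein adjusted p was 7.79e-08 without lv_nc replicate 2, and the mitochondrial one 0.038 without lv_nc replicate 1. Limma called 0 genes of these lists, and 0 adjusted over the list alone. DESeq2 adjusted that way called 1 ferroptosis gene higher and 1 lower.

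**Figure D3:**
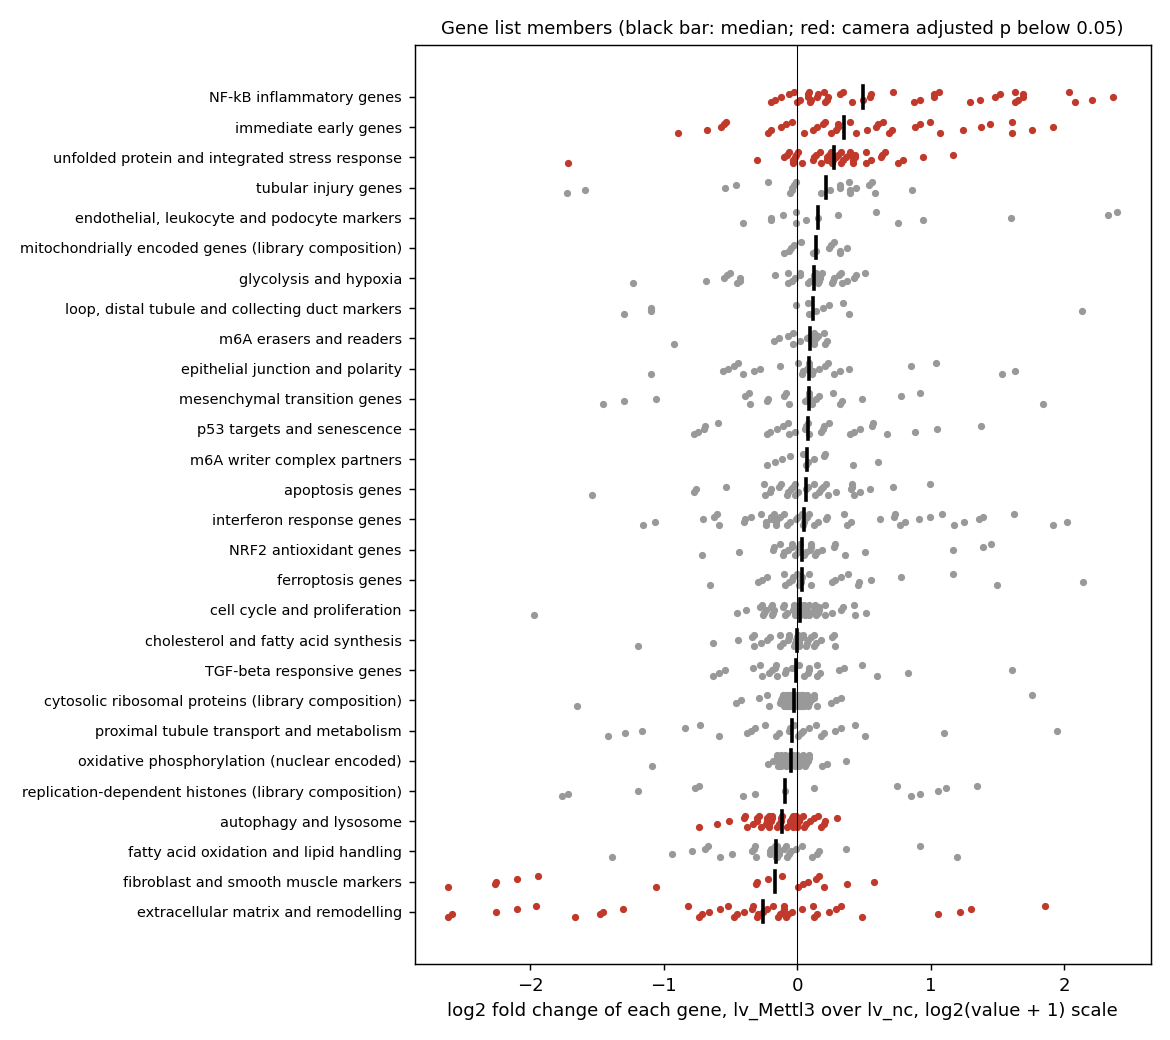
Limma log2 fold change of each tested member (points) of 28 gene lists, lv_Mettl3 over lv_nc, with the list median as a black bar and lists with a camera adjusted p below 0.05 in red. The highest median was 0.49 for NF-kB inflammatory genes and the lowest -0.25 for extracellular matrix genes.

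The authors' deposited table gives fold changes and adjusted p-values for the same comparison. An adjusted p below 0.05 was given to 318 genes in the authors' deposited table, 183 higher and 135 lower, and DESeq2 on the recovered reads called all 318. Log2 fold changes in the authors' deposited table and in that DESeq2 fit differed by at most 7.8e-05. Limma called 3 of the 318. The authors' deposited short list holds 167 genes, 90 higher and 77 lower. For Mettl3 the authors' deposited table gives a log2 fold change of -0.03 and an adjusted p of 0.996.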

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

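TMM scaling of the limma values, robust empirical Bayes, gene-length centring and the alternatives of the DESeq2 count were chosen after seeing the data. The current edgeR quasi-likelihood method and camera on edgeR counts had been planned as the main tests for raw counts, and their use on recovered reads as alternatives was chosen after seeing the data, while edgeR's earlier quasi-likelihood method was chosen before. The limma count of 3 genes, and its count at 2-fold or more, were each 5 with at least 1 CPM in all 4 libraries, protein-coding genes only, both edgeR methods or limma-voom, and 0 with a pseudocount of 0.1 or an adjusted p below 0.01. They were 24 and 23 with robust empirical Bayes and 318 and 167 with DESeq2. Without 1 library each was 0 to 0, with fewer samples and the lone library assumed to vary like the other group. The share of calls that were higher was 79.17% with robust empirical Bayes and 57.55% with DESeq2, against 100%. Authors' calls also called numbered 5 with edgeR, 318 with DESeq2 and 167 with DESeq2 at 2-fold or more, against 3. The DESeq2 count of 318 was 165 at an adjusted p below 0.01 and 56 to 1547 without 1 library; 291 of the 318 were shared without lv_nc replicate 1, 154 without lv_nc replicate 2, 39 without lv_Mettl3 replicate 1 and 45 without lv_Mettl3 replicate 2. The cause was not tested. DESeq2's size factors are the deposited scale and gave no separate setting.

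The replicate numbers give 2 pairs, too few to show pairing; deviations of same-numbered libraries correlated at 0.325 over 10050 genes. With a replicate block limma called 3 genes, but not the same 3: Cxcl10 lost its call (adjusted p = 0.0506) and Ccl2 gained one (0.0469). DESeq2 called 272, of which 237 were among the 318, and Mettl3 was at -0.03. The block ended no call of a list and gave fatty acid oxidation an adjusted p of 0.0246.

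Mettl3 was called in no alternative, with log2 fold changes from -0.08612 to 0.02747 and a change of sign without lv_nc replicate 2 (0.0173) and without lv_Mettl3 replicate 2 (0.02747). Of 1622 values of 82 other named genes, 1498 kept direction and side of the threshold, 17 lost the limma call, 82 passed the threshold of the alternative and 25 changed sign. Of the 82, 61 were in tests on the recovered reads (55 in DESeq2) and 21 in other limma-trend settings (15 with robust empirical Bayes). Of the 17, 15 were the 3 called genes with a pseudocount of 0.1 or without 1 library, and the other 2 were Cxcl10 with library size scaling (0.0502) and with the replicate block. Cxcl10 is among the 50 most abundant genes and has no value without them. Sign changes without 1 library had these lowest and highest log2 fold changes: COX1 -0.01302 and 0.0758, Cd14 -0.06627 and 0.1942, Ctsb -0.05626 and 0.08029, Ftl1 -0.2682 and 0.06692, Hist1h1c -0.2065 and 0.02999, Hnrnpa2b1 -0.07493 and 0.01743, Prrc2a -0.1986 and 0.05962, Rpl3 -0.08677 and 0.09743, Rrm1 -0.1242 and 0.1699, Synpo -0.2493 and 0.2345, Top2a -0.2635 and 0.3517. With library size scaling COX1, Ctsb, Rpl3 and Rrm1 were -0.008568, -0.02794, -0.03462 and -0.01714, with upper-quartile scaling Ctsb and Rpl3 -0.009003 and -0.01568, with gene-length centring Rpl3 -0.006017, and with TMM Synpo 0.000318. The cause was not tested.

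The 6 called lists kept their direction in every alternative run, and lost the call with an estimated correlation and with fry. Fibroblast and smooth muscle markers also lost it with at least 1 CPM in all 4 libraries (0.0544) and without lv_nc replicate 1, lv_Mettl3 replicate 1 or lv_Mettl3 replicate 2, and autophagy without lv_nc replicate 2 or lv_Mettl3 replicate 1. Lists not called passed the threshold in some alternatives: tubular injury with camera on edgeR counts (0.0197), limma-voom (0.0315), DESeq2 (0.0126) and 1 CPM in all 4 libraries (0.0204), interferon with camera on edgeR counts (0.000774), DESeq2 (0.000561) and without the 50 most abundant genes (0.0463), p53 with DESeq2 (0.0411), fatty acid oxidation with TMM (0.048), without the 50 most abundant genes (0.0463) and with a pseudocount of 0.1 (0.0494), and NRF2 with camera on edgeR counts (0.0087), DESeq2 (0.00636), 1 CPM in all 4 libraries (0.0437) and without the 50 most abundant genes (0.0481). Direction was kept in these alternatives. Of the lists not called, 13 changed direction in some other alternative, interferon and fatty acid oxidation among them. Without 1 library their lowest and highest adjusted p were: TGF-beta 0.726 and 0.968, cell cycle 0.000566 and 0.97, cholesterol synthesis 0.146 and 0.76, ribosomal proteins 7.79e-08 and 0.81, fatty acid oxidation 0.000187 and 0.76, glycolysis 0.00404 and 0.97, interferon 2.25e-08 and 0.515, distal tubule 0.357 and 0.961, erasers and readers 0.176 and 0.753, mesenchymal 0.767 and 0.97, mitochondrial 0.038 and 0.899, proximal tubule 0.76 and 0.986, histones 0.366 and 0.986. Direction also changed for mesenchymal genes with camera on edgeR counts (0.801), DESeq2 (0.723) and without the 50 most abundant genes (0.922), for proximal tubule with no filter (0.74), and for histones with fry (0.933) and protein-coding genes only (0.97). Depth, from 15068898 to 16622255 reads, limits low genes most.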

Other observations

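The tests below on Mettl3, on lv_nc replicate 2, on copies, on ERK genes and on other splits were chosen only after the results were seen. The test of fibroblast markers was fixed before the values of that list were seen, when those of the collagens and Acta2 were already known. The genes of the next paragraph were picked after their values were seen.

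Of single genes, these were lower in DESeq2: Tef, at 659 and 1347 in lv_nc and 305 and 375 in lv_Mettl3 (DESeq2 adjusted p = 1.73e-05), Dbp (adjusted p = 0.0084), Per3 (adjusted p = 0.0187) and Nr1d1 (adjusted p = 0.0377), with log2 fold changes of -1.56, -1.59, -1.12 and -0.71. Per1 and Per2 had DESeq2 log2 fold changes of -0.19 and 0.19 and were not called. No list of clock genes was fixed or tested, so nothing is said of them as a group. Spry1, Dusp4 and Tgfa were higher in DESeq2, with log2 fold changes of 1.53, 1.96 and 1.12. None of these genes was called by limma.

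Mettl3 was not higher in the libraries labelled lv_Mettl3. A swap of labels needs libraries that differ in Mettl3, and the highest was 1.10 times the lowest, which argues against a swap as the reason, provided that the reads of the transgene were counted. The murine cDNA may have given reads that were not counted in the rat gene. Among 945 unnamed transcripts 0 were described as Mettl3, but a transgene need not form such a transcript, so uncounted reads cannot be told apart from an absence of added Mettl3 mRNA.

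Collagen genes were lower in the libraries labelled lv_Mettl3, and a smaller share of fibroblast-like cells would lower their other markers by about as much. The median log2 fold change of 14 non-collagen markers was -0.0553 (95% bootstrap bounds -0.312 and 0.14), which argues against a loss of cells that made all of them, although the 14 went both ways (7 above 0) and Ogn and Mcam, at DESeq2 log2 fold changes of -2.03 and -2.51 (adjusted p over the list alone 0.0257 and 0.00709), were lower by about as much as the collagens. Tagln and Acta2, the most abundant, had means of 2720 and 1139 in lv_nc and 2156 and 515 in lv_Mettl3; 5 of the 14 are in another list and 12 kept a mean of at least 20 in lv_Mettl3, so markers made by the epithelial cells themselves may hide a smaller loss, and a loss of cells that made only some of the markers stays open. For lv_nc replicate 2 alone as the source, lv_nc replicate 1 should match the lv_Mettl3 libraries. Over 45 matrix genes its median log2 ratio to them was 0.139 (bounds 0.0423 and 0.324), against 0.237 for replicate 2. Here and for the markers above, the bounds cover the spread over genes, which are not independent, and not that between libraries. They cannot show how far libraries differ in this measure without a cause, so a deviation of lv_nc replicate 2 alone stays open for the matrix genes as a whole. For the collagens called by DESeq2, lv_nc replicate 1 was itself above both lv_Mettl3 libraries. It had 3914 for Col1a1 (1033 and 876 in lv_Mettl3), 4115 for Col3a1 (1386 and 1017) and 86.0 for Col1a2 (28.6 and 16.5). These values argue against lv_nc replicate 2 as the only source for these genes, which were picked as called genes. A difference between separately made stable lines stays open and was not tested, as does the labelled treatment.

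Some genes called by DESeq2 had very large fold changes. Reads shared with near-identical copies may account for part of them. Of 25 called protein-coding genes with an absolute log2 fold change of at least 2.5, 3 had a same-named or same-described copy in the table, 12% against 1.47% of the other called genes, a ratio of 8.16 (2-sided Fisher's exact p = 0.0148). At limits of 1.5, 2 and 3 the ratios were 6.55, 8.57 and 6.59, with Fisher's exact p = 0.0188, 0.00739 and 0.0547. Most of the 25 had no copy found this way, and copies described in other words were missed. Senp5 and LOC103689978, both among the 25, are such a pair. Copies were also more frequent among genes that varied within a label. Of 11200 protein-coding genes at a mean of at least 20, 2.96% had a copy. Of the 113 with replicates 4-fold or more apart, 17.7% had one (odds ratio 7.44, Fisher's exact p = 9.76e-11). Sharing of reads therefore cannot be told apart from changes in the genes themselves.

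A hypothesis from the sprouty, ETS and Fosl1 genes is a higher output of the ERK pathway, the kinase cascade that induces them. Of 18 ERK output genes, 10 were in no fixed list, and these had a median log2 fold change of 0.36 and a camera p of 0.00492, but p = 0.175 with an estimated correlation. All 18 gave p = 0.000478, and 0.107 with an estimated correlation. Fos and Egr1, in that list, had log2 fold changes of -0.89 and -0.57. The test leaves the hypothesis open, and mRNA levels do not measure kinase activity.

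Of the 3 splits of the 4 libraries into pairs, 1, the real one, gave as many DESeq2 calls, with 318 against at most 29 in the others. With 3 splits a share under 0.05 cannot be reached. Each of the other splits puts lv_nc and lv_Mettl3 libraries in the same group. A difference between the labels then adds to the spread within groups and lowers the calls. Their counts therefore do not show how many calls libraries without a difference would give.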
